A study of Mus musculus with 12 samples.

How the data were processed

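RNA was measured in mouse regulatory T cells from wild-type mice and from mice in which Foxp3-driven Cre recombinase removes a loxP-flanked Gpx4 (Foxp3Cre Gpx4fl/fl, called Gpx4-deficient here). Per the labels, the mice were 11 weeks old. Cells were taken either unstimulated or after 4 hours on plate-bound antibodies to CD3 and CD28 at 5 µg/ml. The labels give no time in culture for the unstimulated cells, so effects of stimulation and of culture cannot be told apart. Libraries were made from 600 ng of RNA with a stranded mRNA (poly(A)) kit. The labels give 4 groups, which are wild-type and Gpx4-deficient cells in both states, with 3 libraries in each, for 12 libraries. Each column of the deposited table was matched to its sample by the sample's title, and no column was left unmatched.

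The deposited table holds RSEM gene-level expected counts, which the authors made from the reads and which need not be whole numbers. The build is GRCm38 per the submitters' processing notes. The aligner and the software versions are not given in the sources used here. The table lists 24502 genes by symbol, and between 14.8% and 18.1% of the values in a library were not whole. Expected counts were rounded to whole numbers before testing. Library totals ran from 24629230 to 31879267 counts, so that a level of 5 CPM (counts scaled to library size) stood for 123 reads in the smallest library. The coordinates given come from the GENCODE annotation of GRCm38.

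Groups were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersion, TMM scaling). Genes were kept by the filterByExpr function of that package, which left 14827 genes. All 12 libraries entered one fit of 4 group means with 8 residual degrees of freedom. The comparisons were Gpx4-deficient against wild type without stimulation and with stimulation, stimulated against unstimulated in each genotype, and the interaction. The interaction is the stimulation response of Gpx4-deficient cells minus that of wild-type cells. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Levels are CPM as mean ± SD over the 3 libraries of a group, and fold changes are log2 values with a standard error (SE) derived from the F statistic of edgeR. Every adjusted p of a gene is from this edgeR test unless another tool is named.

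Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes. The adjustment covered the 43 lists, each with at least 5 tested genes. The same test with an estimated correlation and the fry test of limma were run beside it. The lists were ferroptosis defence, ferroptosis drivers and markers, NRF2 targets, selenoproteins other than Gpx4, mitochondrial antioxidants, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, glycolysis, cholesterol biosynthesis, and fatty acid synthesis and desaturation. Stress lists were the ATF4 integrated stress response, the unfolded protein response, p53 targets, apoptosis regulators and heat shock. T cell lists were the early T cell receptor (TCR) response, immediate early genes, NF-kB targets, the interleukin-1 (IL-1) family and inflammasome, Th17, Th1 and cytotoxic, Th2, Treg core signature, effector Treg, naive and central T cell genes, costimulation and checkpoint, and migration and chemokine receptors. Growth lists were cell cycle G2/M, cell cycle S, ribosome biogenesis and MYC targets, ribosomal proteins and replication-dependent histones. The others were interferon-stimulated genes, sex-linked genes and the markers of B cells, plasma cells, monocytes and macrophages, dendritic cells, neutrophils, CD8 and NK cells, erythroid cells and platelets, conventional CD4 T cells, and stromal and epithelial cells. Of the list members, 20 of 29 in the effector Treg list and 11 of 26 in the Treg core list belong to another list too.

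The tests, the lists, the main alternatives and the rule for naming genes were fixed before the data were examined. That rule names Gpx4 and Foxp3 throughout. It also names the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1 and with every library of one group above every library of the other. For the interaction it names the 5 smallest p in each direction, and for each list up to 4 members in order of adjusted p. Receptor and immunoglobulin gene segments and sex-linked genes were left out of the largest changes and are given as groups. Not every gene that the rule picks is described in the text, and 1 of them is not reported here. For a gene at 0 in all libraries of one group, the fold is a lower bound against a floor of 3 counts over the group. A gene with 1 to 3 counts in one group is given as a ratio with its exact 95% counting interval. Floors and intervals cover counting error only. Setting such genes to their bounds moved the median of the histone list by 0.20 (log2) in the stimulated genotype comparison, that of the Th17 list by -0.10 and that of the Th2 list by -0.08 in the unstimulated one. In the genotype and stimulation comparisons every other list median moved by at most 0.04 in size, and the interaction was not examined in this way.

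The fit was tested on simulated data, in which 100 genes were changed by 2-fold and 100 by 8-fold. Each gene was drawn with a single spread for all groups, pooled over the 12 libraries. Common dispersions of the real groups ran from 0.333 to 1.38, so the simulated counts do not cover unequal spread between groups. In the unstimulated genotype comparison it called 9 of the 100 genes changed 2-fold and 52 of the 100 changed 8-fold, with 1 false call in 14245 tested genes. In the stimulated genotype comparison it called 8 and 44, with 1 false call. For stimulation it called 13 and 48 in wild-type cells and 10 and 45 in Gpx4-deficient cells, with 2 and 0 false calls. For the interaction it called 2 and 25, with 1 false call. Lists were tested in the simulated unstimulated genotype comparison alone, where camera called the list raised on purpose and 0 of 40 unchanged lists. The simulated genes were drawn independently, so this cannot show how the preset correlation fares for lists whose genes move together.

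Alternatives were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no filter, a filter of 5 CPM in 3 libraries, a minimum change of 1 on the log2 scale, the replicate number as a block or as a random effect, the 6 libraries of each comparison alone, and leaving out each library in turn. Genes at 50 CPM or more on average, a correction for GC content and transcript length, and leaving out 2 libraries at once were added after the data were seen. A GC content was found for 98.1% of the tested genes. Replicates were checked for shared libraries, and no pair of one group differed as little as sampling noise, with a chi-square per degree of freedom of at least 40.3. The labels state no batch, no sex and no separate animals.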

Results

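Gpx4 encodes a selenoprotein that reduces lipid hydroperoxides in membranes, and its loss from regulatory T cells defines the groups compared here. The gene lies on chromosome 10 from 80047166 to 80056439 (GRCm38, plus strand). Its level in the unstimulated wild-type libraries was 147.1, 172.1 and 141.9 CPM in replicates 1 to 3, and in the stimulated ones 107.5, 82.8 and 69.2 CPM. In the Gpx4-deficient libraries it was 4.96, 7.30 and 12.3 CPM without stimulation and 3.34, 9.23 and 8.52 CPM with it. The group means were 153.7 ± 16.2 CPM against 8.20 ± 3.77 CPM without stimulation (SD, n = 3) and 86.5 ± 19.4 CPM against 7.03 ± 3.22 CPM with it. The remaining Gpx4 signal was thus 5.34% and 8.13% of the wild-type mean. Gpx4 fell in both states, with log2 fold changes of -4.23 (SE 0.45, adjusted p = 0.00458) and -3.62 (SE 0.43, adjusted p = 0.00171) by the edgeR quasi-likelihood test. These calls held without any 1 library of their comparison. Stimulation itself did not change Gpx4 past the edgeR threshold in wild-type cells (log2 fold change -0.83, adjusted p = 0.233) or in Gpx4-deficient cells (-0.22, adjusted p = 0.78).

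Foxp3, the transcription factor that defines the lineage, lies on chromosome X from 7573644 to 7595245 (plus strand) and was present in every group. Its level was 23.8 ± 3.09 CPM in unstimulated wild-type cells, 31.4 ± 7.89 CPM in unstimulated Gpx4-deficient cells, and 37.7 ± 5.16 CPM and 63.9 ± 14.5 CPM after stimulation. Foxp3 was not called between the genotypes by the edgeR test without stimulation (log2 fold change 0.40, adjusted p = 1) or with it (0.76, adjusted p = 0.193). In simulated data the stimulated comparison called 8 of 100 genes changed 2-fold, so a missing call does not show equal levels.

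Whole libraries were also compared before any gene. The 12 libraries held between 24629230 and 31879267 counts, and between 13981 and 17577 genes had at least 1 count. Genes at 0 although they reached 5 CPM in the mean of the other libraries numbered 18.3 ± 4.51 in unstimulated wild type, 35 ± 23.6 in unstimulated Gpx4-deficient, 53.3 ± 24.7 in stimulated wild type and 145.7 ± 41.8 in stimulated Gpx4-deficient libraries. The stimulated Gpx4-deficient libraries also had the lowest correlations between replicates (0.795 to 0.820 across genes, against 0.916 to 0.921 in unstimulated wild type), and the widest spread (common dispersion 1.38 against 0.333). Mitochondrially encoded transcripts made up 3.19 ± 0.467% of their counts, against 1.27 ± 0.0973% in stimulated wild type, 1.79 ± 0.130% in unstimulated Gpx4-deficient and 1.32 ± 0.0907% in unstimulated wild-type libraries. In a principal component analysis (components 1 and 2 held 28.9% and 14.9% of the variance) stimulated Gpx4-deficient replicate 3 lay apart from replicates 1 and 2 on component 2 (175.6 against -79.0 and -62.6), and unstimulated Gpx4-deficient replicate 1 from replicates 2 and 3 (64.8 against 25.2 and 14.9). Stimulated Gpx4-deficient replicate 3 also had the most genes at 0 (190) and the highest mitochondrial share (3.72%, against 2.84% and 3.01% in replicates 1 and 2). Nothing in the labels says that libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical. Library identifiers run in separate blocks for each genotype, so that genotype and any library batch cannot be told apart.

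**Figure D1:**
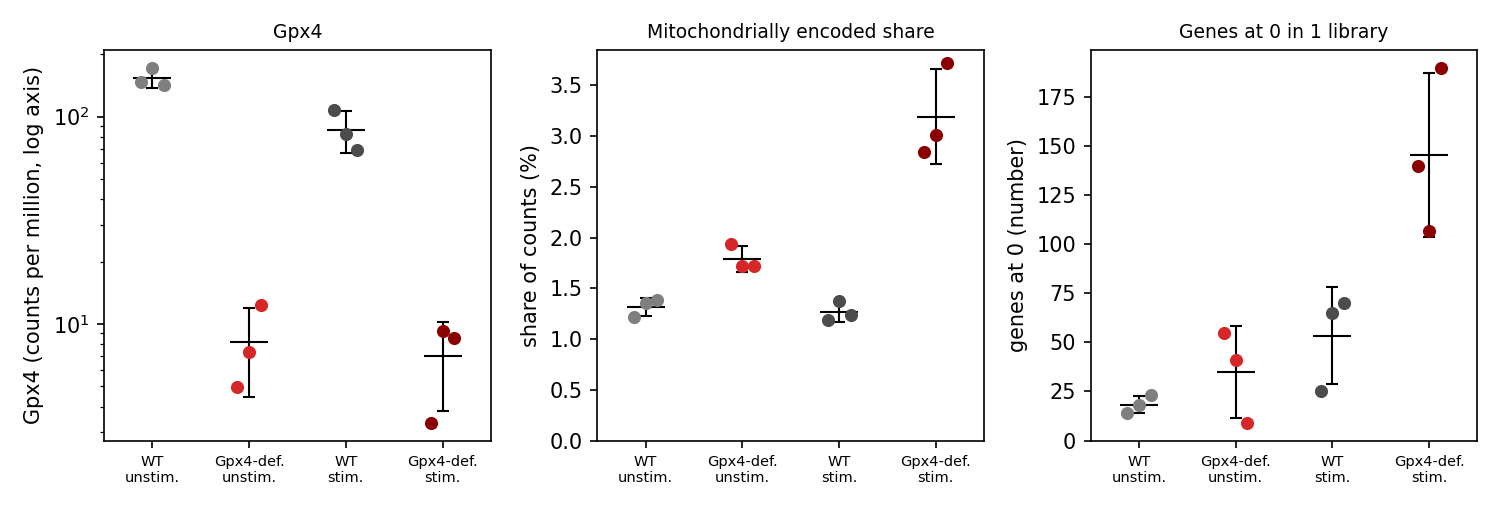
Gpx4 level (CPM, log axis), share of counts from mitochondrially encoded transcripts (%) and number of genes at 0 though at 5 CPM or more in the mean of the other libraries, with a point for each of the 12 libraries and bars for the group mean ± SD. The 3 stimulated Gpx4-deficient libraries had 107 to 190 such genes, and those of the other groups had 9 to 70.

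The first comparison asks how Gpx4-deficient and wild-type cells differ without stimulation. The sample titles call the controls only WT, so an effect of Cre recombinase may be part of any genotype difference. Among the 8 genes called higher, transcripts for inducible heat shock proteins had the largest fold changes. Hspa1a and Hspa1b encode nearly identical HSP70 chaperones that refold damaged proteins. Hspa1a (chromosome 17, 34969190 to 34972156, minus strand) rose from 367.2 ± 27.7 to 2867.67 ± 542 CPM, a log2 fold change of 2.97 (SE 0.29, adjusted p = 0.00458, edgeR). Hspa1b (34956436 to 34959238, minus strand) rose from 836.6 ± 97.1 to 5001.94 ± 885 CPM (log2 fold change 2.58, SE 0.35, adjusted p = 0.0236, edgeR). The 2 transcripts share 2222 of the 2803 bases of Hspa1b, so reads cannot always be assigned to one of them, and their sum went from 1224.76 ± 106 to 7883.62 ± 1501.83 CPM. Dnajb1, an HSP40 partner of those chaperones, rose from 319.5 ± 16.8 to 730 ± 52.9 CPM (1.19, SE 0.14, adjusted p = 0.00785, edgeR). Hspa8, the constitutive HSP70, rose from 2083.78 ± 109 to 3972.52 ± 864 CPM (0.93, SE 0.13, adjusted p = 0.0272, edgeR). Of 15 tested heat shock genes, 4 rose, 9 rose when adjusted over the list alone, and 15 had a positive log2 fold change (list median 0.87, camera adjusted p = 4.74e-15, and 0.00867 with an estimated correlation).

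Immediate early genes, which code for transcription factors and phosphatases induced within minutes by many signals, were also higher in unstimulated Gpx4-deficient cells. Fos rose from 1498.53 ± 199 to 3307.20 ± 90.7 CPM (log2 fold change 1.14, SE 0.14, adjusted p = 0.00785, edgeR), and Jun, its partner in AP-1, from 1056.94 ± 114 to 2248.85 ± 163 CPM (1.09, SE 0.15, adjusted p = 0.0243). Dusp1, a phosphatase of MAP kinases, rose from 2039.42 ± 123 to 3061.79 ± 150 CPM (0.59, SE 0.08, adjusted p = 0.0236). In that list 3 of 17 tested genes rose and 11 did when adjusted over the list alone (median 0.74, camera adjusted p = 2.90e-11, and 0.0301 with an estimated correlation). H2-Q6, a class I histocompatibility gene, rose from 697.2 ± 22.3 to 1040.51 ± 72.1 CPM (0.58, SE 0.08, adjusted p = 0.0243). Besides Gpx4, the gene that fell was Gm4366, from 102.8 ± 32.4 to 9.67 ± 2.84 CPM (-3.41, SE 0.37, adjusted p = 0.00458). Gm4366 is a processed pseudogene on chromosome 7 (116824510 to 116825851, minus strand), and 1337 of its 1342 bases match Eef1g, so its count depends on how reads are shared with that gene.

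**Figure D2:**
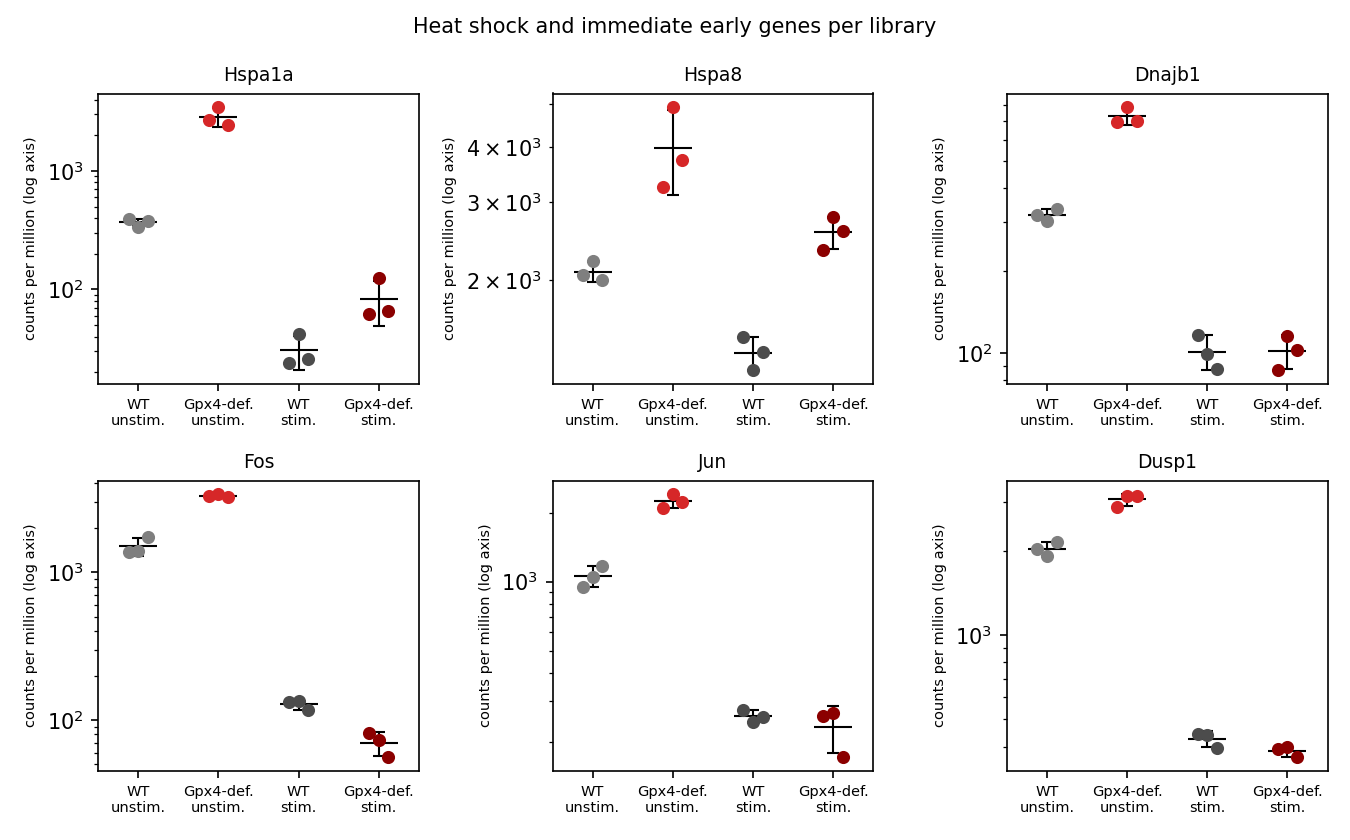
Levels (CPM, log axis) of the heat shock genes Hspa1a, Hspa8 and Dnajb1 and the immediate early genes Fos, Jun and Dusp1, with a point for each of the 12 libraries and bars for the group mean ± SD. Hspa1a stood at 367.2 CPM in unstimulated wild type and 2867.67 CPM in unstimulated Gpx4-deficient cells, and Fos fell with stimulation in both genotypes.

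Proliferation genes were lower in unstimulated Gpx4-deficient cells as lists. All 24 tested G2/M genes and all 24 S phase genes had negative log2 fold changes, with medians of -0.94 (camera adjusted p = 1.16e-10) and -0.72 (1.84e-09). Both calls held with an estimated correlation (adjusted p = 0.00867 each). None of these 48 genes passed over all genes, while 7 G2/M and 5 S phase genes fell when adjusted over the list alone. A further 8 lists were called by camera but not with an estimated correlation. Nuclear oxidative phosphorylation genes were lower (65 tested, median -0.27, adjusted p = 1.15e-08, and 0.185 with an estimated correlation). Mitochondrially encoded genes were higher, 11 of 13 when adjusted over the list alone and 0 over all genes (median 0.50, 1.95e-08, and 0.255 with an estimated correlation). Neutrophil markers (10 tested, median -3.69, 4.93e-05, and 0.179), replication-dependent histones (48, -0.42, 0.00481, and 0.102), glycolysis (19, -0.29, 0.0111, and 0.312) and interferon-stimulated genes (32, -0.42, 0.0111, and 0.358) were lower by camera. Neutrophil markers summed to 116.6 ± 66.2 CPM in wild-type and 32.6 ± 25.8 CPM in Gpx4-deficient cells. IL-1 family and inflammasome genes (16, 0.46, 0.0142, and 0.102) and ribosomal proteins (79, 0.07, 0.0271, and 0.734) were higher by camera. Adjusted over the list alone, 5 glycolysis genes fell and 1 IL-1 family gene rose.

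Lists close to the function of Gpx4 did not move by camera in unstimulated cells. The adjusted p was 0.717 for ferroptosis defence (median 0.05), 0.647 for ferroptosis drivers and markers (-0.15), 0.97 for NRF2 targets, 0.131 for other selenoproteins and 0.098 for mitochondrial antioxidants. The Treg core (adjusted p = 0.979) and effector Treg lists (0.252) were not called either. Median, mean and camera direction differed in sign for the ATF4 list (median 0.07, mean 0.28, tested lower), Th1 (-0.04, 0.17, higher), conventional CD4 T cell genes (0.09, -0.08, higher), plasma cell (0.39, 0.15, lower), CD8 and NK (-0.33, 0.29, lower), stromal (0.16, -0.45, lower), Treg core (-0.02, 0.02, lower) and early TCR response lists (-0.02, 0.04, higher). None of these 8 was called.

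By edgeR 10 genes changed without stimulation, 8 higher and 2 lower, and in all 10 the 3 libraries of one genotype lay above the 3 of the other. The count depended on the method, at 3 (1 higher and 2 lower) with the replicate number as a block, 77 (43 and 34) with limma-voom and 183 (101 and 82) with DESeq2. Among all tested genes 18.3% showed such separation, where chance gives 10%. Unadjusted p was under 0.05 for 860 genes, where 741.4 would be by chance. Without 1 library, Gpx4, Hspa1a and Gm4366 kept their calls each time. Without wild-type replicate 1 the count was 3, without wild-type replicate 2 it was 3, and without Gpx4-deficient replicate 2 it was 5. Hspa1b lost its call without wild-type replicates 1, 2 or 3 (edgeR adjusted p = 0.161, 0.17 and 0.0839) or Gpx4-deficient replicate 2 (0.0809), and Dnajb1 without wild-type replicates 1 or 2 (0.0623 and 0.0847). Fos lost it without wild-type replicates 1 or 2 (0.109 and 0.115) or Gpx4-deficient replicate 2 (0.0711), and Dusp1 without those 3 libraries (0.161, 0.17 and 0.104) or Gpx4-deficient replicate 3 (0.0591). Jun lost it without any 1 of the 6 libraries (0.0602 to 0.228), Hspa8 without wild-type replicates 1, 2 or 3 (0.109 to 0.161), and H2-Q6 without those or Gpx4-deficient replicate 2 (0.0809 to 0.159). Of the lists, glycolysis lost the camera call without wild-type replicate 1 or Gpx4-deficient replicate 3 (0.0904 and 0.0628), the IL-1 family without wild-type or Gpx4-deficient replicate 3 (0.0821 and 0.0665), interferon-stimulated genes without wild-type replicate 3 or Gpx4-deficient replicate 2 (0.5 and 0.0584), and ribosomal proteins without wild-type or Gpx4-deficient replicate 1 (0.513 and 0.8).

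The next comparison asks how the genotypes differ in cells stimulated for 4 hours through CD3 and CD28. Transcripts of the mitochondrial genome rose as a group. Mitochondrial cytochrome b (mt-Cytb) rose from 2339.43 ± 59.6 to 6230.97 ± 958 CPM (log2 fold change 1.41, SE 0.11, adjusted p = 0.000134, edgeR). The complex I subunits mt-Nd2 (264.4 ± 20.7 to 826 ± 136 CPM, 1.64, SE 0.13, adjusted p = 0.000134) and mt-Nd5 (561 ± 77.2 to 1898.17 ± 243 CPM, 1.76, SE 0.15, adjusted p = 0.000222) rose too. The ATP synthase subunits mt-Atp6 (1.51, SE 0.13, adjusted p = 0.000222) and mt-Atp8 (2.44, SE 0.32, adjusted p = 0.00251) rose as well. In all, 11 of 13 mitochondrially encoded genes rose and 12 did when adjusted over the list alone (median 1.54, camera adjusted p = 9.51e-20, and 0.0686 with an estimated correlation). Of 65 nuclear oxidative phosphorylation genes 2 fell, Ndufb5 and Atp5b, and 6 fell when adjusted over the list alone. That list had a median of 0.04 and a mean of -0.03, was higher by the test direction and was not called by camera (adjusted p = 0.836). The calls of the mitochondrial genes named here held without any 1 library. Ndufb5 lost its call without wild-type replicates 1, 2 or 3 or Gpx4-deficient replicate 1 (0.0637 to 0.159), and Atp5b without any 1 library except Gpx4-deficient replicate 1 (0.085 to 0.184).

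Effector Treg genes were higher in stimulated Gpx4-deficient cells, and Treg core genes went both ways. Icos, a costimulatory receptor of effector Treg cells, rose from 949.8 ± 23.5 to 1974.03 ± 252 CPM (log2 fold change 1.06, SE 0.11, adjusted p = 0.000582, edgeR). Itgae, the CD103 integrin chain that binds E-cadherin, rose from 84.6 ± 21.0 to 196.4 ± 24.6 CPM (1.22, SE 0.19, adjusted p = 0.00832), and Il1r2, a decoy receptor for IL-1, from 382.2 ± 47.4 to 640.9 ± 80.6 CPM (0.75, SE 0.13, adjusted p = 0.0134). Maf, a transcription factor of effector cells, rose from 55.4 ± 12.6 to 164.4 ± 34.9 CPM (1.57, SE 0.27, adjusted p = 0.0134), but not without wild-type replicate 1 or 3 (0.0663 and 0.0572). Ikzf2, which encodes Helios, rose from 587.5 ± 68.6 to 895.6 ± 51.4 CPM (0.61, SE 0.11, adjusted p = 0.0203), but not without the same replicates (0.0904 and 0.0705). The checkpoint receptor gene Tigit rose from 139.3 ± 9.33 to 242.4 ± 37.2 CPM (0.80, adjusted p = 0.0314), but not without wild-type replicates 1, 2 or 3 or Gpx4-deficient replicate 3 (0.0904, 0.0735, 0.0946 and 0.0686). Of 29 effector Treg genes 5 rose and 0 fell, and 6 rose when adjusted over the list alone (median 0.37, camera adjusted p = 0.000915, and 0.0460 with an estimated correlation). Of 26 Treg core genes 3 rose, and adjusted over the list alone 7 rose and 5 fell, Tnfrsf18 (-0.60), Swap70 (-0.65) and Lrrc32 (-0.33) among the falls, 3 genes chosen after their values were seen (list median 0.16, camera adjusted p = 0.0301, and 0.0841 with an estimated correlation). The camera call of the Treg core list did not hold without Gpx4-deficient replicate 3 (0.103), and the summed level of that list was 21424.89 ± 711 CPM in wild-type and 20438.32 ± 289 CPM in Gpx4-deficient cells.

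By camera, ribosome biogenesis, cholesterol biosynthesis, cell cycle and ATF4 lists were lower in stimulated Gpx4-deficient cells. Ribosomal proteins, histones and fatty acid synthesis were not called. Phgdh, which starts serine synthesis, fell from 1350.53 to 612.2 CPM (log2 fold change -1.14, SE 0.16, adjusted p = 0.00473, edgeR). Mcm3, a subunit of the replicative helicase, fell from 203.5 ± 20.1 to 69 ± 22.7 CPM (-1.56, SE 0.20, adjusted p = 0.00239). Cad, which starts pyrimidine synthesis, fell from 238.8 to 102.2 CPM (-1.23, SE 0.21, adjusted p = 0.0111), but not without wild-type replicate 1 (0.068). Ldha, lactate dehydrogenase, fell from 1519.61 ± 270 to 779.7 ± 137 CPM (-0.96, SE 0.18, adjusted p = 0.0218), but not without wild-type replicate 1 or 3 (0.0911 and 0.0559). Ribosome biogenesis and MYC targets were lower (4 of 26 fell, 10 when adjusted over the list alone, median -0.47, camera adjusted p = 0.000131). Cholesterol biosynthesis was lower too (0 of 23 fell, 6 when adjusted over the list alone, median -1.01, camera adjusted p = 0.000131). Both calls held with an estimated correlation (0.0460 each). S phase genes (24 tested, 2 fell, 4 over the list alone, median -0.44, camera adjusted p = 0.000731) and G2/M genes (24 tested, 1 fell, 2 over the list alone, -0.36, 0.00465) were lower but not with an estimated correlation (0.0686 and 0.0875). The ATF4 integrated stress response (24 tested, 2 fell, 6 when adjusted over the list alone, -0.44, camera adjusted p = 0.00465, and 0.0686 with an estimated correlation) was lower as well.

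Single genes of signalling, survival and heat shock changed too. Nr4a1, induced by the T cell receptor, fell from 3174.19 ± 27.5 to 1582.57 ± 206 CPM (log2 fold change -1.004, SE 0.12, adjusted p = 0.00187, edgeR). Bcl2l1, which encodes the survival protein BCL-XL, fell from 512.8 ± 9.43 to 279.1 ± 27.2 CPM (-0.88, SE 0.13, adjusted p = 0.00565). Fos fell from 127.7 ± 10.2 to 70.1 ± 12.9 CPM (-0.86, SE 0.14, adjusted p = 0.0076), although it was higher in the same genotype without stimulation. Junb fell from 1207.46 ± 121 to 692.7 ± 99.6 CPM (-0.80, SE 0.13, adjusted p = 0.0104). Fos and Junb lost these calls without wild-type replicate 1 (0.0572 and 0.0742) or 2 (0.0621 and 0.0723). Over all genes 3 of 17 immediate early genes fell, and adjusted over the list alone 4 fell and 2 rose (median -0.14, camera adjusted p = 0.441). Of 24 early TCR response genes 2 fell, and 6 did when adjusted over the list alone (median -0.25, camera adjusted p = 0.172). Hspa8 rose from 1369.35 ± 118 to 2562.73 ± 215 CPM (0.90, SE 0.13, adjusted p = 0.00585). Hspa1a and Hspa1b rose too, from 30.5 ± 9.77 to 83.7 ± 34.6 CPM and from 26.5 ± 7.61 to 99.7 ± 48.8 CPM (1.46 and 1.91, adjusted p = 0.0215 and 0.0174). They lost the call without wild-type replicate 3 (0.0919 and 0.0557), Hspa1a also without wild-type replicate 1 (0.104) and Hspa1b without wild-type replicate 2 (0.0676). Of 15 heat shock genes 3 rose, and adjusted over the list alone 8 rose and 2 fell (median 0.28, camera adjusted p = 0.0137, and 0.266 with an estimated correlation). That camera call did not hold without Gpx4-deficient replicate 2 or 3 (0.0866 and 0.0993).

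Among the largest changes with stimulation, several genes were at or near 0 in one genotype. Pif1, a DNA helicase, was at least 142-fold lower in Gpx4-deficient cells, and the uncharacterised 6330403K07Rik at least 74.8-fold lower. Kifc1, a mitotic kinesin, had a ratio of 486 (95% counting interval 86.8 to 19243.45) and Metrn, which codes for a secreted factor, one of 477 (85.1 to 18877.77). In the other direction Ntn4, a laminin-related netrin, was higher by a ratio of 818 (146.5 to 32354.63). Clock, a circadian transcription factor, rose from 14.1 ± 4.21 to 89.0 ± 35.4 CPM (log2 fold change 2.66, SE 0.36, adjusted p = 0.00343, edgeR). Fam49a, a regulator of actin, rose from 12.5 ± 2.47 to 69.1 ± 27.4 CPM (2.47, SE 0.36, adjusted p = 0.00538), and the pseudogene Tdg-ps2 from 0.670 ± 0.409 to 37.4 ± 12.6 CPM (5.79, SE 0.89, adjusted p = 0.00714). Of the 185 genes that fell, 49 were at 0 in at least 1 Gpx4-deficient library and 16 in all 3. Falls also outnumbered rises among genes with a mean log2 CPM of 0 to 2, by 64 to 4. Median GC content was 51.4% in the genes that fell, 45.95% in those that rose and 49.0% in all tested genes.

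Markers of other cell types were compared as lists. Of 10 dendritic cell markers Cd74 rose, from 259.8 ± 41.9 to 544.7 ± 51.2 CPM (log2 fold change 1.07, SE 0.16, adjusted p = 0.0056, edgeR), and 2 rose when adjusted over the list alone (median 0.66, camera adjusted p = 0.280). The summed level of that list was 380.1 ± 83.2 CPM in stimulated wild type and 744 ± 106 CPM in stimulated Gpx4-deficient cells. Jchain, which joins antibody chains, rose from 20.7 ± 4.70 to 102.2 ± 25.4 CPM (2.31, SE 0.41, adjusted p = 0.0142), but not without wild-type replicate 1 or 2 (0.0706 and 0.0582). It was the 1 plasma cell marker of 6 that rose (median 0.44, camera adjusted p = 0.366). Monocyte and macrophage markers summed to 159 ± 43.5 and 265.8 ± 42.2 CPM (16 tested, 0 called, 2 higher when adjusted over the list alone, median 2.34, camera adjusted p = 0.0724). Erythroid and platelet markers were higher by camera, at 16.0 ± 11.1 and 45.7 ± 5.99 CPM in sum (7 tested, 0 called, median 1.14, adjusted p = 0.0129, and 0.0758 with an estimated correlation), but not without any 1 of 5 of the libraries (all except wild-type replicate 2, 0.0702 to 0.103). Neutrophil markers (10 tested, median 0.00, mean -0.66, adjusted p = 0.568), B cell markers (11, 1.00, mean -0.43, tested higher, 0.836), CD8 and NK markers (10, -0.83, 0.568), stromal markers (5, -2.97, 0.304), conventional CD4 T cell genes (14, 0.23, 0.467) and sex-linked genes (5, 0.40, 0.208) were not called. Igf1r rose in the conventional CD4 list (1.13), but not without any 1 of 5 of the libraries (all except Gpx4-deficient replicate 1, 0.0517 to 0.122). Receptor and immunoglobulin segments held 213 tested genes, of which 2 rose and 0 fell.

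Other lists called by camera in stimulated cells were lost with an estimated correlation. IL-1 family genes were higher (16 tested, 1 rose, 4 when adjusted over the list alone, median 0.91, camera adjusted p = 0.0137, and 0.0758 with an estimated correlation), as were migration and chemokine receptor genes (22 tested, 1 rose and 1 fell, 5 and 1 when adjusted over the list alone, 0.43, 0.0372, and 0.206). Ferroptosis drivers and markers (13 tested, 0 called, -0.48, 0.0446, and 0.310) and glycolysis (19 tested, 1 fell, 3 when adjusted over the list alone, -0.36, 0.0495, and 0.323) were lower. The camera call of ferroptosis drivers ended without any 1 of the 6 libraries (0.0565 to 0.205). That of glycolysis ended without wild-type replicates 1, 2 or 3 or Gpx4-deficient replicate 2 (0.217, 0.0529, 0.104 and 0.256). The IL-1 family call ended without wild-type replicate 2 or 3 or Gpx4-deficient replicate 2 (0.053, 0.0767 and 0.0866), and the migration call without wild-type replicate 3 or Gpx4-deficient replicate 1 or 3 (0.0767, 0.166 and 0.106).

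Ferroptosis defence was not called (16 tested, median -0.12, camera adjusted p = 0.498). Its member Fth1, the ferritin heavy chain that stores iron, rose from 1353.61 ± 40 to 1767.64 ± 56.4 CPM (log2 fold change 0.39, SE 0.09, adjusted p = 0.0387, edgeR), but not without any 1 of 5 of the libraries (all except Gpx4-deficient replicate 1, 0.0557 to 0.146). NRF2 targets (21 tested, 0.13, camera adjusted p = 0.472) and other selenoproteins (17, median -0.09, mean -0.35, tested higher, 0.981) had 0 called members. Mitochondrial antioxidants (14, -0.31, 0.174) had 1 fall, Txn2 (-0.74), but not without any 1 of the same 5 libraries (0.0869 to 0.192). Camera also left uncalled fatty acid synthesis (-0.12, adjusted p = 0.446), the unfolded protein response (median -0.01, mean 0.03, 0.743), p53 targets (-0.30, 0.220), apoptosis regulators (0.08, 0.643), NF-kB targets (median -0.13, mean 0.17, tested lower, 0.568), Th17 (0.47, 0.0601), Th1 (median 0.10, mean -0.52, tested higher, 0.825), Th2 (0.29, 0.539) and naive T cell genes (0.32, 0.225). The same held for interferon-stimulated genes (-0.29, 0.280), costimulation genes (-0.30, 0.568), ribosomal proteins (0.08, 0.208) and histones (-0.44, 0.296). Adjusted over the list alone, naive T cell genes had 4 rises and 1 fall, costimulation genes 3 and 4, ribosomal proteins 3 and 4 and NF-kB targets 1 and 4.

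By edgeR 337 genes changed in stimulated cells, 152 higher and 185 lower, and 212 of them by 2-fold or more. The balance depended on level, since a fit of the genes at a mean of 50 CPM or more called 253 higher and 160 lower. In 336 the 3 libraries of one genotype lay above the 3 of the other, while 20.2% of all tested genes did so and chance gives 10%. This count depended on single libraries, at 117, 158 and 164 without wild-type replicates 1, 2 and 3, and at 658 and 625 without Gpx4-deficient replicates 1 and 2. It also depended on the method, at 22 with the 6 libraries alone, 95 with limma-voom (70 higher and 25 lower) and 1564 with DESeq2. Of the 22 calls, 10 were mitochondrially encoded genes, and of the 58 genes called here and named by the rule, the 6 libraries alone ended 49 calls and limma-voom 35.

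Stimulation of wild-type cells shows the response against which the mutant response is set. It is the change after 4 hours of culture with antibodies, so culture alone may account for part of it. Genes downstream of the T cell receptor rose. Nr4a3, an orphan nuclear receptor, rose from 34.7 ± 1.64 to 883 ± 139 CPM (log2 fold change 4.67, SE 0.18, adjusted p = 2.60e-08, edgeR), and Irf4, needed for effector Treg cells, from 53.1 ± 9.38 to 736.4 ± 50.2 CPM (3.79, SE 0.15, adjusted p = 4.28e-08). Il2ra, the high-affinity IL-2 receptor chain, rose from 524.3 ± 16.4 to 2522.47 ± 173 CPM (2.27, SE 0.09, adjusted p = 4.28e-08). Lrrc32, which displays latent TGF-beta, rose from 482.1 ± 40.3 to 2326.15 ± 148 CPM (2.27), Tnfrsf9 by a log2 fold change of 3.55 and the chemokine receptor gene Ccr8 by 3.04. In the early TCR response list 19 of 24 genes rose (20 when adjusted over the list alone, median 2.28, camera adjusted p = 9.21e-25). The Treg core list (15 of 26 rose and 5 fell, 17 and 5 over the list alone, median 0.93, 2.58e-08), costimulation (12 of 20 rose and 1 fell, 12 and 1, 1.56, 2.58e-08), NF-kB targets (11 of 20 rose and 3 fell, 13 and 3, 0.59, 0.00047), Th17 (6 of 18 rose, 7, 1.25, 0.000266) and Th2 genes (3 of 10 rose, 6, 1.99, 0.00047) were higher. So was the effector Treg list (12 of 29 rose and 6 fell, 14 and 7 when adjusted over the list alone, 0.71, camera adjusted p = 0.0044). The Th1 list was higher by camera but not with an estimated correlation (7 of 18 rose and 1 fell, 7 and 2, 0.54, 0.00967, and 0.0655). Il22 was at least 121-fold higher.

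Genes of the ATF4 and ribosome biogenesis lists rose in wild-type cells. Slc7a5, a transporter of large neutral amino acids, rose from 32.1 ± 1.03 to 419.4 ± 22.7 CPM (log2 fold change 3.71, SE 0.16, adjusted p = 5.67e-08, edgeR). Asns, asparagine synthetase, rose by 6.003 (SE 0.77, adjusted p = 0.000266) and Chac1, which degrades glutathione, by 8.60 (SE 0.79, adjusted p = 1.78e-05). In the ATF4 list 18 of 24 genes rose and 1 fell (20 and 1 when adjusted over the list alone, median 2.59, camera adjusted p = 1.40e-19). Ncl, nucleolin, rose from 735.3 ± 12.4 to 2102.64 ± 118 CPM (1.52, SE 0.08, adjusted p = 2.41e-07), with 25 of 26 ribosome biogenesis genes (26 over the list alone, median 1.46, camera adjusted p = 2.88e-23). Slc7a11, the cystine transporter that feeds glutathione synthesis, was at least 159.5-fold higher, and Slc3a2, its partner chain, rose by 2.25 (SE 0.10, adjusted p = 5.54e-08). Tfrc, the transferrin receptor, rose from 40.3 to 235.8 ± 36.6 CPM (2.55, SE 0.30, adjusted p = 0.000129). Ferroptosis defence (3 of 16 rose, 3 when adjusted over the list alone, median 0.30, camera adjusted p = 0.0225) and ferroptosis drivers (4 of 13 rose, 4 over the list alone, 0.72, 0.000567) were higher, both with an adjusted p of 0.0610 with an estimated correlation. NRF2 targets (4 of 21 rose and 2 fell, adjusted p = 0.302) and other selenoproteins (1 of 17 rose and 4 fell, 0.208) were not called.

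Other groups were lower after stimulation of wild-type cells, and the labels describe no cultured control without antibodies. Fos fell from 1498.53 to 127.7 CPM (log2 fold change -3.55, SE 0.15, adjusted p = 4.45e-08, edgeR), Dusp1 from 2039.42 to 425.8 ± 27.3 CPM (-2.26, SE 0.08, adjusted p = 2.19e-08) and Hspa1b by a log2 fold change of -4.98 (SE 0.40, adjusted p = 5.60e-06). Immediate early genes went both ways, with 5 of 17 higher and 9 lower, and the same numbers when adjusted over the list alone (median -0.74, mean 0.30, tested lower, camera adjusted p = 0.167). Of 15 heat shock genes 2 rose, Hspd1 among them, and 5 fell (median -0.13, camera adjusted p = 0.167). Interferon-stimulated genes fell (1 of 32 rose and 8 fell, 1 and 18 when adjusted over the list alone, median -2.33, camera adjusted p = 1.60e-08), as did naive and central T cell genes (1 of 18 rose and 9 fell, 1 and 11, -1.58, 4.46e-05). Igfbp4, a binding protein for insulin-like growth factors, fell from 383.2 to 12.2 CPM (-4.98, SE 0.36, adjusted p = 2.55e-06). S phase (6 of 24 fell, 7 over the list alone, -0.81, camera adjusted p = 0.00033), G2/M (5 of 24, 6, -0.88, 0.00047) and histone lists (1 of 48, 1, -1.84, 4.02e-08) were lower. Monocyte and macrophage markers were lower too (3 of 16 fell, 4 over the list alone, -2.89, camera adjusted p = 0.000638), and their sum was 579.8 ± 103 CPM before and 159 ± 43.5 CPM after stimulation. Migration genes (4 of 22 rose and 10 fell, 4 and 11 when adjusted over the list alone, -1.23, camera adjusted p = 0.0152, and 0.101 with an estimated correlation), erythroid markers (0 of 7 fell, 3, -2.03, 0.0117, and 0.0536) and oxidative phosphorylation genes (2 of 65 rose and 2 fell, 2 and 1, -0.23, 0.0270, and 0.456) were lower by camera alone. The oxidative phosphorylation call ended without unstimulated replicate 2 (0.126) or stimulated replicate 1 (0.108), and the erythroid call without unstimulated replicate 1 (0.0564). Mitochondrially encoded genes were not called (0 of 13 changed, median 0.09, camera adjusted p = 0.380), and neither were glycolysis (0.878), cholesterol biosynthesis (0.878), fatty acid synthesis (0.612), the unfolded protein response (0.518), p53 targets (0.206), apoptosis regulators (0.0827), the IL-1 family (0.777) and ribosomal proteins (0.71).

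By edgeR 1709 genes changed with stimulation of wild-type cells, 907 higher and 802 lower, and 1226 by 2-fold or more. In 1708 of them the groups lay fully apart, as in 41.98% of all tested genes, where chance gives 10%. Leaving out each library in turn gave counts of 1150 to 1248, and other methods gave 2639 (DESeq2), 3499 (edgeR on the 6 libraries alone) and 3998 (limma-voom). Of the 21 called lists, 15 held with an estimated correlation.

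Many of the same genes moved in stimulated Gpx4-deficient cells, again with culture not separated from stimulation. Nr4a3 rose from 22.6 to 679.6 ± 106 CPM (log2 fold change 4.91, SE 0.18, adjusted p = 2.38e-08, edgeR), Il2ra from 522.3 to 2934.22 ± 273 CPM (2.49, SE 0.09, adjusted p = 2.38e-08) and Icos from 340.5 ± 34.4 to 1974.03 CPM (2.54, SE 0.11, adjusted p = 7.35e-08). The early TCR response (19 of 24 rose, 20 when adjusted over the list alone, median 1.73, camera adjusted p = 2.32e-19), ribosome biogenesis (23 of 26 rose, 23, 1.20, 5.16e-15), ATF4 (18 of 24 rose and 1 fell, 18 and 1, 2.18, 7.00e-13) and Treg core lists (19 of 26 rose and 4 fell, 19 and 4, 1.33, 3.40e-10) were higher. So were costimulation (12 of 20 rose and 1 fell, 12 and 2 when adjusted over the list alone, median 1.58, camera adjusted p = 1.56e-06), Th17 (5 of 18 rose, 9, 2.77, 1.64e-05), effector Treg (14 of 29 rose and 4 fell, 16 and 6, 1.01, 5.61e-05), Th2 (4 of 10 rose, 4, 2.08, 0.00139), NF-kB (9 of 20 rose and 3 fell, 10 and 3, 0.73, 0.00442) and apoptosis regulator lists (5 of 20 rose and 1 fell, 6 and 1, 0.41, 0.00681). Called in both genotypes, 665 genes rose in both (67.6 by chance) and 552 fell in both (62.8 by chance), and 3 moved in opposite directions. Across genes the 2 responses correlated with a Pearson coefficient of 0.42 over all tested genes (Spearman 0.51) and 0.87 over the 4293 genes at 50 CPM or more, and genes are not independent replicates.

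Mitochondrially encoded, immediate early, heat shock, cholesterol and apoptosis regulator lists were called in Gpx4-deficient and not in wild-type cells, which does not show that the responses differed, and the other lists below were called in both. mt-Cytb rose from 2815.66 ± 311 to 6230.97 CPM (log2 fold change 1.15, SE 0.11, adjusted p = 2.01e-05, edgeR), with 11 of 13 mitochondrially encoded genes (11 when adjusted over the list alone, median 1.18, camera adjusted p = 7.31e-09, and 0.140 with an estimated correlation). Foxp3 rose (1.03, SE 0.29, adjusted p = 0.0325), but not without unstimulated replicates 1, 2 or 3 (0.0588, 0.0562 and 0.122) or stimulated replicates 2 or 3 (0.0889 and 0.0585). Il1r2 rose by 2.71 (SE 0.14, adjusted p = 1.53e-07). Fos fell from 3307.20 to 70.1 CPM (-5.56, SE 0.16, adjusted p = 3.45e-09) and Hspa1a by a log2 fold change of -5.10 (SE 0.32, adjusted p = 8.80e-07). Immediate early genes (4 of 17 rose and 9 fell, 5 and 9 when adjusted over the list alone, median -1.08, camera adjusted p = 0.00516, and 0.196 with an estimated correlation) and heat shock genes (1 of 15 rose and 8 fell, 2 and 9, -0.51, 0.00733, and 0.182) were lower. Cholesterol biosynthesis was lower (4 of 23 fell, 4 over the list alone, -0.62, camera adjusted p = 0.0102, and 0.0841 with an estimated correlation), and Srebf2, which drives it, fell (-0.79, SE 0.14, adjusted p = 0.00225). Interferon-stimulated genes (1 of 32 rose and 12 fell, 1 and 16 when adjusted over the list alone, -1.55, camera adjusted p = 1.56e-06, and 0.0786) and S phase genes (5 of 24 fell, 5, -0.74, 0.0044, and 0.0786) were lower without holding with an estimated correlation. Histones (5 of 48 fell, 3 when adjusted over the list alone, -1.23, camera adjusted p = 2.98e-05) and naive T cell genes (1 of 18 rose and 9 fell, 3 and 11, -1.33, 0.00235) were lower and held. The Th1 list was higher by camera (7 of 18 rose and 3 fell, 9 and 5 when adjusted over the list alone, 1.05, 0.0333, and 0.140 with an estimated correlation), but not without unstimulated replicate 3 or stimulated replicates 2 or 3 (0.0577, 0.0527 and 0.071).

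Capn3, a calcium-activated protease, fell from 76.4 ± 6.27 to 0.068 CPM in Gpx4-deficient cells (log2 fold change -10.02, SE 0.47, adjusted p = 1.14e-07, edgeR). Pif1 was at least 395-fold lower and Acad10, an acyl-CoA dehydrogenase, had a ratio of 2104.03 (95% counting interval 377 to 83147.19). By edgeR 2266 genes changed, 1105 higher and 1161 lower, and 1673 by 2-fold or more, with leave-one-out counts of 1649 to 2521. Other methods gave 1022 (edgeR on the 6 libraries alone), 1476 (limma-voom) and 3609 (DESeq2). Of the falls 270 had at least 1 stimulated library at 0 and 110 had all 3, against 49 and 21 of the 802 falls in wild-type cells. The groups lay fully apart in 2203 of the called genes and in 29.8% of all genes, where chance gives 10%. Camera did not call ferroptosis defence (4 of 16 rose, adjusted p = 0.247), ferroptosis drivers (5 of 13 rose, 0.121), NRF2 targets (6 of 21 rose and 3 fell, 0.168), G2/M (1 of 24 fell, 0.0623), monocyte markers (1 of 16 fell, 0.144), migration genes (0.51) or ribosomal proteins (3 of 79 rose and 12 fell, 0.653). Signs differed for p53 targets (median -0.39, mean -0.15, tested higher), dendritic cell markers (0.23, -0.68, lower), erythroid markers (0.82, -0.22, higher) and conventional CD4 T cell genes (-0.01, 0.20, lower), none of them called.

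The interaction asks whether the stimulation response differs between genotypes. With stimulation, several immediate early genes rose less or fell further in Gpx4-deficient than in wild-type cells. Fos fell by 5.56 in them and by 3.55 in wild type on the log2 scale, an interaction of -2.01 (SE 0.19, adjusted p = 0.00206, edgeR). In that list 6 of 17 genes passed as lower, among them Junb, Ier2 and Dusp1, and 8 did when adjusted over the list alone (median -0.96, camera adjusted p = 1.43e-06, and 0.115 with an estimated correlation). Capn3 gave -5.51 (SE 0.52, adjusted p = 0.00206). Mitochondrially encoded genes rose with stimulation in Gpx4-deficient cells relative to wild type, led by mt-Nd2 (1.15, SE 0.18, adjusted p = 0.0294), with 2 of 13 past the threshold and 11 when adjusted over the list alone (median 1.06, camera adjusted p = 9.20e-13, and 0.12 with an estimated correlation). S100a10, a partner of annexin A2, was 313.1 ± 36.7 and 249.5 ± 12.5 CPM without stimulation and 93.9 ± 5.71 and 172.2 ± 27.8 CPM with it, in wild-type and Gpx4-deficient cells (1.20, SE 0.20, adjusted p = 0.0405). By edgeR 30 genes passed, 4 higher and 26 lower, and 1298 had an unadjusted p under 0.05, where 741.4 would by chance. A fit of the genes at a mean of 50 CPM or more called 17 higher and 13 lower, and 12 of those were among the first 30. With genotype and replicate number as a block in edgeR 0 genes passed, and Capn3 and Fos lost their calls. The same held with that block as a random effect in limma-voom. Its estimated correlation there was 0.0096, so that fit differed from the edgeR fit mainly in its tool. Limma-voom with sample weights called 4 and DESeq2 380. In the fit without a block Capn3 and Fos kept their calls without each of the 12 libraries. mt-Nd2 (0.0654 to 0.144), S100a10 (0.0733 to 0.144), Ier2 (0.0618 to 0.144) and Dusp1 (0.0712 to 0.167) lost theirs without any 1 of the 9 libraries outside the stimulated Gpx4-deficient group, and Junb without those except unstimulated Gpx4-deficient replicate 3 (0.0697 to 0.144). The count fell to 2 without any 1 of the unstimulated wild-type libraries, and was 3, 3 and 12 without unstimulated Gpx4-deficient, 8, 6 and 10 without stimulated wild-type, and 131, 167 and 67 without stimulated Gpx4-deficient replicates 1 to 3. Of 13 lists called by camera, 0 held with an estimated correlation (adjusted p = 0.115 to 0.437).

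**Figure D3:**
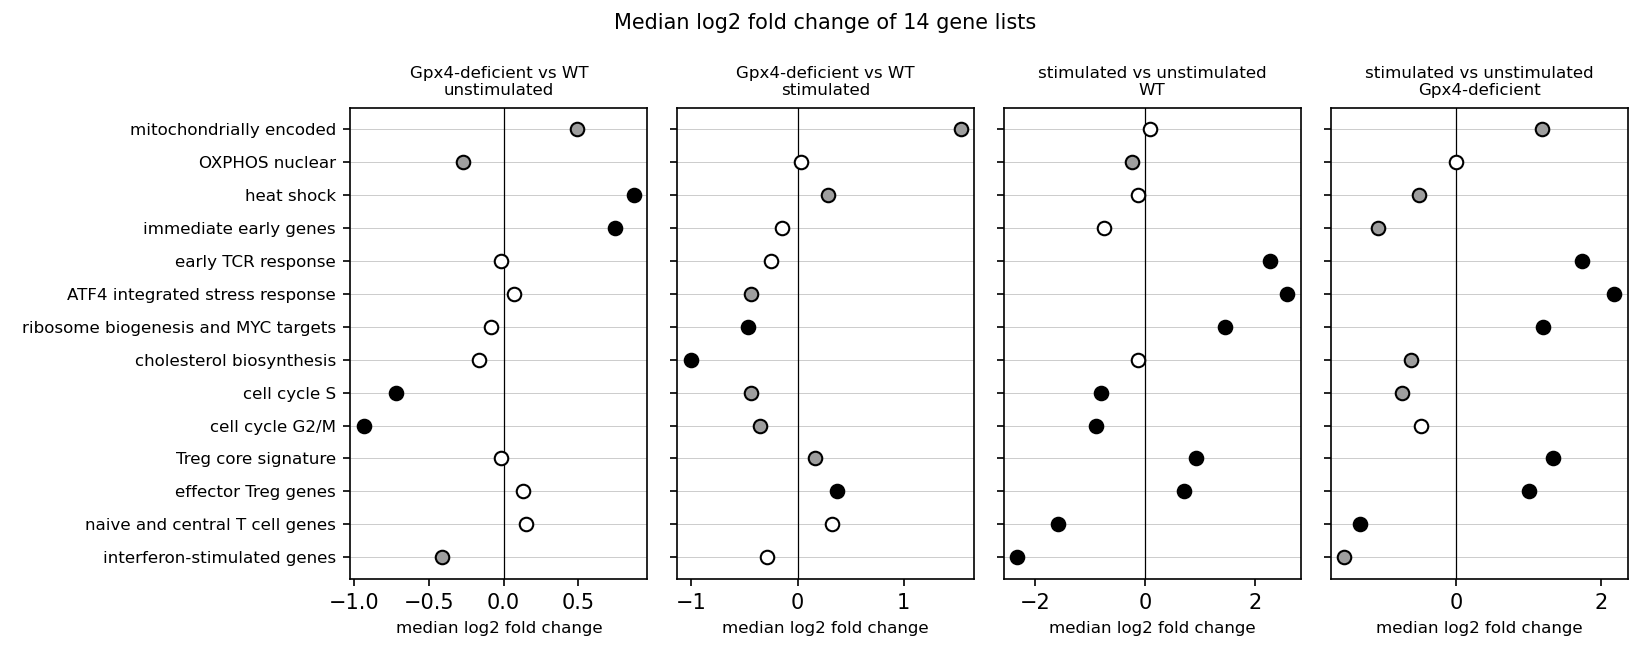
Median log2 fold change of 14 lists in the 2 genotype and the 2 stimulation comparisons (one panel each, with its own axis), with black points for lists called by camera and also with an estimated correlation, grey points for lists called by camera alone and open points for lists not called. The heat shock list stood at 0.87 without stimulation and the mitochondrially encoded list at 1.54 with stimulation.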

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

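The other splits of the libraries, the test of nuclear genes matched in level and the test of genes at 0 in all 3 libraries were planned, while the tests of GC content and length, of a batch, of handling and of the remaining libraries were chosen only after the result was seen. Batch and handling were first read from camera with an estimated correlation or from the number of called members, and fry replaced both as the test after those values were known. The results given here are those whose response to stimulation differed between the genotypes by the interaction term. By edgeR 30 genes differed (0 with the replicate block, 4 by limma-voom and 380 by DESeq2), and by camera 13 lists did, with 0 lists at an estimated correlation. Groups of 3 libraries are too small for a test of single outlying samples, though stimulated Gpx4-deficient replicate 3 lay apart on principal component 2 (175.6 against -79.0 and -62.6).

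The genes with the smallest p in each direction, or named through a list, were as follows. Stimulation raised mt-Nd2 by 1.15 and mt-Cytb by 0.92 more (log2) in Gpx4-deficient than in wild-type cells, and Icos by 0.89 more. S100a10 gave 1.20, as it fell less in Gpx4-deficient cells. Fos (-2.01), Egr1 (-1.43), Nr4a1 (-1.28), Junb (-1.27), Ier2 (-1.13), Dusp1 (-0.73) and Dnajb1 (-1.19) had a negative interaction. That means a smaller rise or a larger fall with stimulation in Gpx4-deficient cells, and Fos fell further in them. Capn3 (-5.51), Cd72 (-7.11), Cenpj (-6.40) and Tbxa2r (-5.06) were near 0 in the stimulated Gpx4-deficient libraries, so these fitted sizes depend on the prior count and are no bounds. Capn3 and Fos kept their calls without each of the 12 libraries. Cd72 lost it without unstimulated wild-type replicates 1, 2 or 3 (edgeR adjusted p = 0.0551 to 0.0615), and Cenpj and Tbxa2r without those or unstimulated Gpx4-deficient replicates 1 or 2 (0.0516 to 0.107 and 0.0504 to 0.107). Nr4a1 (0.0504 to 0.144), Egr1 (0.0918 to 0.18) and Junb (0.0697 to 0.144) lost it without any 1 of the unstimulated or stimulated wild-type libraries or unstimulated Gpx4-deficient replicates 1 or 2. The calls of mt-Nd2 (0.0654 to 0.144), mt-Cytb (0.0542 to 0.144), S100a10 (0.0733 to 0.144), Icos (0.0549 to 0.167), Ier2 (0.0618 to 0.144), Dusp1 (0.0712 to 0.167) and Dnajb1 (0.0697 to 0.167) ended without any 1 library outside the stimulated Gpx4-deficient group.

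The list medians of the difference were 1.06 for mitochondrially encoded genes, 0.28 for nuclear oxidative phosphorylation, 0.22 for the Treg core and 0.34 for effector Treg genes. Migration genes gave 0.37, and the marker lists gave 2.16 for monocytes and macrophages, 3.72 for neutrophils and 2.20 for erythroid cells and platelets. In the Gpx4-deficient stimulation comparison 3 of 16, 4 of 10 and 2 of 7 genes of these lists had at most 3 counts in a group. Neutrophil markers summed to 116.6 ± 66.2 CPM before and 55.7 ± 30.9 CPM after stimulation in wild-type cells. In Gpx4-deficient cells they summed to 32.6 ± 25.8 and 45.9 ± 35.9 CPM. Medians were -0.96 for immediate early genes, -0.68 for cholesterol biosynthesis, -0.52 for the ATF4 list, -0.37 for ribosome biogenesis and -0.38 for heat shock. The camera call of Treg core genes ended without unstimulated wild-type replicate 1, unstimulated Gpx4-deficient replicates 2 or 3 or any 1 stimulated Gpx4-deficient library (0.0522 to 0.104), and that of effector Treg genes without unstimulated Gpx4-deficient replicate 3, stimulated wild-type replicate 1 or stimulated Gpx4-deficient replicates 1 or 3 (0.0527 to 0.149). Ribosome biogenesis lost it without unstimulated Gpx4-deficient replicate 2 or stimulated Gpx4-deficient replicates 1 or 2 (0.068 to 0.0773), heat shock without stimulated Gpx4-deficient replicate 1 (0.1), and migration without unstimulated wild-type replicate 1 or stimulated Gpx4-deficient replicates 1 or 3 (0.0542 to 0.102). The monocyte list lost it without replicate 3 of unstimulated or 2 of stimulated wild type, unstimulated Gpx4-deficient replicates 1 or 2 or stimulated Gpx4-deficient replicates 1 or 3 (0.0682 to 0.153). The neutrophil list lost it without 8 of the 12 libraries (all but replicate 1 of either wild-type group, unstimulated Gpx4-deficient replicate 3 and stimulated Gpx4-deficient replicate 1, 0.0868 to 0.297).

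Mitochondrially encoded transcripts were higher in stimulated Gpx4-deficient cells (11 of 13, list median 1.54). Loss of molecules that spares abundant transcripts is argued against, because 182 nuclear genes matched to them in level had a median log2 fold change of -0.015 with an upper quartile of 0.35. A trend of GC content and length is argued against as the whole cause, since 11 members remained higher after it was removed (median 1.19), although 0 members then passed in the interaction (list median 0.63). A library batch that follows genotype and acts alike in both states is argued against as the whole cause, since the list changed in the interaction (fry adjusted p = 0.0103, median 1.06, 11 of 13 members over the list alone), although camera with an estimated correlation gave 0.12. The list was flagged by that same contrast, so this is no separate evidence, and with the replicate block 0 of 13 members passed there. Loss of Gpx4 in activated cells stays open as an untested biological explanation, as does a batch or a change of RNA or cell quality in that group alone.

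Transcripts were lost from the stimulated Gpx4-deficient libraries, where 354 of 9930 genes at 5 CPM or more elsewhere were at 0 in at least 1 library. Random loss alike for genes of one level is argued against for the 20 genes at 0 in all 3 libraries, since 1.24 (SD 1.11) would be met by chance, though an excess also occurred in unstimulated wild type (6 against 0.00904) and in the other groups (2 and 5). For the 334 genes at 0 in 1 or 2 libraries random loss stays open. In the remaining libraries the median log2 ratio of these genes to stimulated wild type was -0.13 (quartiles -1.50 and 0.63). That ratio leaves out libraries at 0 in Gpx4-deficient cells but not in wild type, which raises it, so it cannot decide. GC content and length are argued against as the whole cause of the called falls, of which 145 of 185 remained after that trend was removed (183 had a GC value). Falls resting on a library at 0 are thus open to loss of molecules, and a biological loss of the 20 genes is a hypothesis.

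Heat shock and immediate early genes were higher in unstimulated Gpx4-deficient cells. A batch acting alike on all Gpx4-deficient libraries is argued against as the whole cause, since the lists were lower in the interaction, immediate early genes with 6 called members (fry adjusted p = 0.00583) and heat shock genes with 1 (0.0176), and Fos was called in opposite directions in the 2 states. Handling of the unstimulated cells alone is argued against as the whole cause for heat shock genes, since the list was higher in stimulated cells too (fry adjusted p = 0.0225), Hspa8 among its 3 called members. With an estimated correlation camera called none of these 3 results (adjusted p = 0.115, 0.1996 and 0.2655). The 2 interaction results come from the contrast that flagged these lists, so they are no separate evidence. Both groups react to cell isolation, so loss of Gpx4 and a difference in isolation between genotypes, unequal in the 2 states, both stay open.

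Other splits of the same libraries were fitted in the same way. For the 4 comparisons of 3 against 3 libraries there are 10 splits each, too few for a share under 0.05. In each, 1 split, the real one, reached the real count. The real split called 10 genes without stimulation (highest other split 0), 337 with stimulation (2), 1709 for stimulation of wild-type cells (0) and 2266 for stimulation of Gpx4-deficient cells (1). It called 12 lists (highest other 11), 14 (5), 21 (15) and 19 (8). For the interaction, 7 of 100 splits gave 30 genes or more, with 325 the highest other. The 6 other splits at 30 or more kept the stimulated genotype groups whole and so measure the genotype effect, and the highest crosses genotype between the states, which points to the structure of the samples. For its 13 lists, 2 of 100 splits gave as many, with 18 the highest other. Most other splits mix the genotypes within groups, which widens their spread and lowers their counts. These splits thus do not settle whether chance is excluded for the interaction, and 0 of the 13 lists held with an estimated correlation (camera adjusted p = 0.115 to 0.437).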

How the results depend on the processing

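Genes at 50 CPM or more, the correction for GC content and length and the fit without 2 libraries were chosen after the data were seen, and the other alternatives before. No named gene changed direction past a threshold under an alternative that tested it, some of which tested fewer genes, and no called list did in the alternatives run for lists (leaving out libraries, relative log expression, the block, the GC correction, 50 CPM, an estimated correlation and fry). No called gene changed sign when 1 library was left out. Counts of genes are given in the order unstimulated genotype (10 in the fit reported), stimulated genotype (337), stimulation of wild type (1709), stimulation of Gpx4-deficient cells (2266) and interaction (30). DESeq2 called more throughout, 183, 1564, 2639, 3609 and 380. Limma-voom with sample weights called 77, 95, 3998, 1476 and 4. With the 6 libraries of a comparison alone, stimulation of wild type gave 3499, stimulation of Gpx4-deficient cells 1022 and the stimulated genotype comparison 22, and the interaction has no such fit. That setting no longer shares one spread among groups whose common dispersions ran from 0.333 to 1.38. Genes at 50 CPM or more gave 32 for the unstimulated genotype comparison. A change of at least 1 on the log2 scale left 212 for the stimulated genotype comparison, by construction. Without unstimulated Gpx4-deficient replicate 1 and stimulated Gpx4-deficient replicate 3, the 2 libraries of that genotype with most genes at 0 in their state, the interaction gave 57, and stimulation of wild type holds neither library. In that fit 11 of 13 mitochondrially encoded genes were still higher in stimulated Gpx4-deficient cells (list median 1.39). For DESeq2, limma-voom, the 50 CPM count and the 57 the cause was not tested. Counts with relative log expression (11 to 2296), upper-quartile scaling (11 to 2246), no filter (11 to 1963), 5 CPM (12 to 2311) and the GC correction (12 to 2125) stayed within 1.5 times.

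Leaving out 1 library gave 3 to 14, 117 to 658, 1150 to 1248, 1649 to 2521 and 2 to 167 genes, and 10 to 12, 9 to 12, 20 to 22, 18 to 20 and 7 to 12 lists. It ended the call of 7 of the 10 named and called genes, 30 of 58, 27 of 129, 28 of 142 and 14 of 16. Among the same genes the 6 libraries alone ended 49 of 58 calls in the stimulated genotype comparison, limma-voom ended 35 of 58 there and 13 of 16 in the interaction, and the replicate block ended 19 of 58 and 16 of 16. Most named calls of the stimulated genotype comparison thus ended when its 6 libraries were fitted alone. Leaving out the 2 libraries with most genes at 0 ended 9 of those 58 calls. Called lists numbered 12, 14, 21, 19 and 13. An estimated correlation left 4, 3, 15, 12 and 0, which allows for genes that move together. Of the 43 lists tested, none passed for the interaction with it, and 12 did by fry. Fry, which does not compare a list with other genes, called 6, 19, 32, 30 and 12. At 50 CPM or more 9, 9, 13, 13 and 12 lists were called, of fewer lists with 5 genes. Without the 2 libraries, 8 were called for the stimulated genotype comparison and 7 for the interaction, and the cause was not tested.

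With the replicate number as a block in edgeR the gene counts were 3, 171, 1265, 1622 and 0. That block was the number alone for the genotype comparisons, and genotype with number for the others. As a random effect of genotype with number, fitted with limma-voom, the counts were 18, 438, 1874, 2915 and 0. The correlation estimated for that effect was 0.0096, so this fit differed from the edgeR fit mainly in its tool. In the edgeR interaction without a block 1298 genes had an unadjusted p under 0.05, where 741.4 would by chance. Whether the numbers pair the samples stays open. Deviations of same-numbered libraries of one genotype correlated at -0.0224 to 0.0297 over genes in 6 pairs. Of 12 libraries 6 correlated best with their own number among the 3 libraries of their genotype in the other state. These values cover all tested genes, 3632 of them with a mean log2 CPM under 0, so counting noise can hide a pairing. The block costs residual degrees of freedom. Depth was not varied. With a pooled spread per gene, alike in all groups, and 3 libraries in each group, the test on simulated data called 2 to 13 of 100 genes changed 2-fold.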

Other observations

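The genotype effect was compared between the states, in comparisons that share no library. Hspa1a, Hspa1b and Hspa8 rose in both, 3 genes where 0.082 would be shared by chance (Fisher's exact test, p = 5.70e-05). Gpx4, the deleted gene, and the pseudogene Gm4366 fell in both. Fos was the 1 gene called in opposite directions. Of the 337 genes called in stimulated cells, 268 had the same sign without stimulation. Genes of one pathway are not independent, and Hspa1a and Hspa1b share reads, so the Fisher p-value overstates the number of separate events. Both comparisons also come from one fit with a shared spread for each gene, and genotype follows the library identifiers in both states. Of 213 tested receptor and immunoglobulin segments, stimulation gave 0 rises and 12 falls in wild-type cells and 1 rise and 7 falls in Gpx4-deficient cells by edgeR, and most were not called. B cell marker levels summed to 82.8 ± 19.5 CPM in unstimulated and 25.4 ± 7.20 CPM in stimulated wild-type libraries. In unstimulated and stimulated Gpx4-deficient libraries they summed to 62.8 ± 20.8 and 41.8 ± 36.5 CPM. Of the 14 genes in that list, 5 reached 5 CPM in unstimulated wild-type cells.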
